A study of Arabidopsis thaliana with 6 samples.

How the data were processed

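Transcript levels were measured on 6 arrays of one Affymetrix design for Arabidopsis thaliana, each hybridised with biotin-labelled target made from total RNA of whole, untreated plants 21 days old in the vegetative stage. The labels name 2 genotypes with 3 arrays each, the wild type Col-0 and an overexpressor called ARR21C. Replicates were numbered within a genotype for naming only, and nothing in the labels ties an array of one genotype to an array of the other. The labels do not say whether the arrays of a genotype came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

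The deposited values were signal intensities on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes; its version was not given in the sources used here. After trimming 2% at either end, the mean intensity of each deposited array was 100.0, so the authors' values had been scaled by array. The median intensity per array ran from 37.2 to 40.4. No detection calls, scan dates or batches were used, and the number of arrays limits the precision. A batch that follows genotype could not be told apart from it.

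Of 22810 probe sets, 64 AFFX controls were kept out of the comparison of genes. Signals were taken as log2(signal + 16), and probe sets whose mean log2 value lay under the 30th percentile of the 22746 others were left out, which kept 15922. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Log2 differences are the overexpressor minus Col-0 on the log2(signal + 16) scale, which understates the change of dim probe sets. Every adjusted p of a single gene below comes from this limma fit.

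Probe sets were named only through the platform annotation table given, with symbols updated by gene identifier through the RefSeq table of the assembly TAIR10.1. That table pairs 13513 probe sets with 1 gene and 503 with several, and 8730 are unnamed here, of which 6890 were among those kept. Of the 13513 identifiers, 13436 matched the RefSeq table. For a gene with several probe sets, the probe set with the highest mean was taken, which gave 8617 genes.

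Before the data were examined, 24 gene lists with 270 entries, the fits and the rule for named genes were fixed. Only 33 of the entries were named on the array and 28 passed the filter on dim probe sets. The rule named the overexpressed gene first, then the 14 largest increases and the 14 largest decreases past the threshold, with all 3 values of one genotype beyond those of the other, 1 named gene, and a mean signal in the higher genotype at or above the median of that quantity. It also named every type-A response regulator and up to 4 members of each other list. Because so few entries were named, further lists were written by locus after the probe table and the largest changes had been seen. They hold cytosolic and plastid ribosomal proteins, further photosynthesis genes, class III peroxidases, root hair cell wall genes, root-abundant genes and seed maturation genes. They also hold histones, CC-type glutaredoxins, the genes of the plastid genome, mitochondrial genes picked by symbol, and symbol families with at least 8 measured genes. Mitochondrial genes were taken only where the symbol was nad, cox or ccb with a number, or matR. Other genes of that genome were left out. These lists were chosen after seeing the data and are not independent evidence.

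Lists with at least 4 measured members were tested with camera at a preset correlation of 0.01 against the other named genes, adjusted over 2 fixed and, separately, 33 added lists. Camera with an estimated correlation and fry, which tests whether a list moves one way without comparing it with other genes, were run beside it. The 3' to 5' ratios of control transcripts were compared by exact two-sided permutation, whose smallest p for 3 against 3 arrays is 0.1.

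The fit was tested on simulated data with the real means and spreads over the 15922 probe sets kept. At a simulated log2 difference of 2 it recovered 100.0% of the changed probe sets, at 1 it recovered 90.0%, and at 0.5 it recovered 45.0%; at -1 and -0.5 it recovered 93.8% and 39.5%. Of 145 calls, 6 were of probe sets that had not been changed. Only 200 probe sets were changed in the simulation, far fewer than were called in the real data. The Benjamini-Hochberg cutoff depends on that share, so the recovery of small differences does not carry over to the real comparison. The alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter or a filter at the 50th percentile, other variance priors, array weights, leaving out each array, thresholds of 0.01 and 0.1, and for lists the other set tests and the mean over a gene's probe sets.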

Results

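Transcripts of whole 21-day-old Arabidopsis plants were compared between the wild type Col-0 and plants labelled as overexpressing ARR21C, with 3 arrays per genotype. ARR21 is a type-B response regulator, a class of transcription factors at the end of the phosphorelay that carries the cytokinin signal. The label was read only as ARR21C, and the comparison asked which transcripts differ in plants carrying it. ARR21 itself was not analysed here, because 0 probe sets were paired with it in the table used, so the genotype labels were not checked against its signal. Values are MAS5 signals, given as mean ± SD with n = 3 arrays per genotype.

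The genotypes differed in a large part of the transcripts measured. Of 15922 probe sets, 4733 were higher and 4514 lower in the overexpressors at a limma adjusted p under 0.05. At least 2-fold differences were found for 719 higher and 862 lower probe sets. With a pseudocount of 64 these became 362 and 427, and with a pseudocount of 1 they became 1053 and 1295. Log2 signals correlated at 0.990 to 0.993 between arrays of a genotype and at 0.931 to 0.935 between genotypes, across probe sets, which are not independent replicates. Among probe sets paired with 1 gene, 2551 of 8709 were higher and 2270 lower.

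Genes of the cytokinin circuit were among those that rose. Of 10 type-A response regulators in the list, 2 were named and measured. Both of these early cytokinin-response genes, which dampen the signal, were higher in all 3 overexpressor arrays than in any Col-0 array. ARR16 (AT2G40670) rose from 25.2 ± 1.53 to 196 ± 8.45, a log2 difference of 2.36 (SE 0.084, limma adjusted p = 1.1e-11). ARR15 (AT1G74890) rose from 15.0 ± 2.91 to 109 ± 18.0, a log2 difference of 2.01 (limma adjusted p = 2.45e-09). The 2 measured glycosyltransferases that conjugate cytokinins moved apart. UGT76C2 rose from 40.7 ± 3.07 to 210 ± 11.2 (log2 difference 1.99) and UGT76C1 fell from 52.2 ± 10.2 to 29.3 ± 6.95 (log2 difference -0.59, limma adjusted p = 0.00161). Adjusted over the list alone, both type-A regulators and UGT76C2 were higher and UGT76C1 was lower. The type-B regulators ARR18 and ARR19 had mean signals of 6.35 and 4.75 in Col-0 and were under the filter on dim probe sets. Receptors, phosphotransfer proteins, cytokinin biosynthesis genes and other early response genes had 0 members named in the table used. They may lie among the unnamed probe sets, so nothing is known here of their levels.

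**Figure D1:**
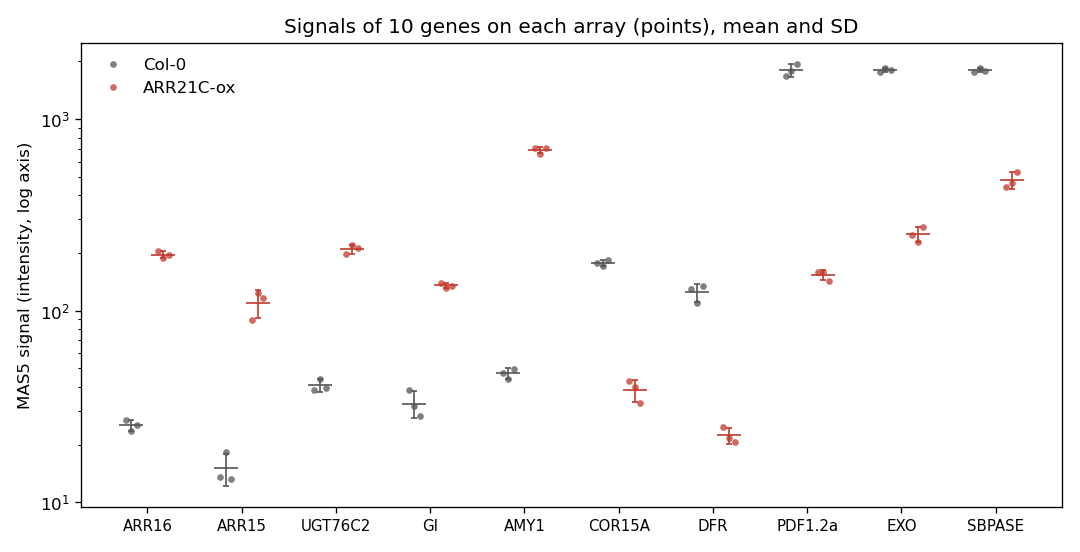
MAS5 signal on a log axis for 10 genes, with Col-0 in grey and the ARR21C overexpressors in red. Points are single arrays, horizontal marks the mean of 3 arrays and bars the SD; in each gene shown the 3 values of one genotype lie beyond those of the other, as for ARR16 at 25.2 against 196 and COR15A at 177 against 38.4.

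The 14 largest increases among named genes had log2 differences from 3.18 to 4.86. AT2G18590 rose from 26.1 ± 5.58 to 1203 ± 84.8, a log2 difference of 4.86 (limma adjusted p = 4e-14). The lipid transfer protein-like genes AT4G12500, AT4G12490 and AT5G38160 rose from 41.0 ± 0.919 to 1128 ± 58.8, from 156 ± 8.93 to 1582 ± 49.0 and from 12.0 ± 2.58 to 325 ± 13.2. The defensin-like gene PDF1.4 rose from 24.3 ± 3.13 to 613 ± 76.6 and the dirigent-like gene AT1G58170 from 21.9 ± 7.44 to 359 ± 24.0. AMY1, an alpha-amylase that degrades starch, rose from 47.0 ± 2.92 to 690 ± 28.7. Further increases were those of the strictosidine synthase-like gene AT1G74010 (log2 difference 4.12), AT5G60630 (3.92), the bHLH gene AT1G10585 (3.81), the oleosin family gene AT3G01570 (3.35), AT5G15190 (3.303), AT3G61930 (3.26) and MPC (3.18), a gene known for maternal expression in the endosperm.

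The 14 largest decreases had log2 differences from -3.54 to -2.26. The thionin gene AT1G66100 fell from 855 ± 13.7 to 59.1 ± 5.35, a log2 difference of -3.54 (limma adjusted p = 5.03e-14). PDF1.2a (AT5G44420), a jasmonate- and ethylene-responsive plant defensin, fell from 1798 ± 132 to 154 ± 9.70. The brassinosteroid-responsive gene EXO fell from 1801 ± 46.4 to 250 ± 22.9, and the endoglucanase-family gene GH9B13 from 226 ± 6.10 to 30.6 ± 1.005. The MATE transporter gene AT3G23550 fell from 645 ± 34.4 to 75.9 ± 20.002 and the lipid transfer protein gene AT5G48490 from 1040 ± 101 to 187 ± 25.3. The remaining decreases were AT1G65490 (log2 difference -2.85), AT5G12050 (-2.77), AT2G04039 (-2.71), AT1G67865 (-2.68), AT3G48420 (-2.50), AT4G38080 (-2.38), AT5G03120 (-2.33) and the PR-1-like gene AT4G33720 (-2.26). The unnamed probe sets chosen by the same rule changed by log2 differences of up to 5.81 and down to -3.65. The signal of 266743_at went from 32.9 ± 4.96 to 2728 ± 202 and that of 250612_s_at from 0.920 ± 0.125 to 820 ± 31.5, while 266353_at fell from 681 ± 47.7 to 39.4 ± 2.65 and 261569_at from 215 ± 29.4 to 4.97 ± 4.08.

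Photosynthesis transcripts were lower in the overexpressors. Of 21 genes in the fixed list of light harvesting and photosystem genes only 4 were measured. All 4 fell, with the same count adjusted over the list alone. The photosystem I subunit gene PSAN fell from 2054 ± 120 to 1073 ± 21.1 (log2 difference -0.93), the antenna genes LHCB4.2 from 2441 ± 153 to 1356 ± 46.3 and LHCB4.1 from 3494 ± 92.1 to 2459 ± 158, and the Rubisco activase gene RCA from 3057 ± 82.8 to 1736 ± 104. The camera adjusted p of this list was 0.000451, but the call was lost with an estimated correlation (adjusted p = 0.103). The further photosynthesis list, and the plastid, mitochondrial, ribosomal, root hair, peroxidase and seed maturation lists, were written after the largest changes had been seen and are not independent evidence of a direction. Of 46 genes in the further photosynthesis and Calvin cycle list only 9 were measured. All 9 fell, with a median log2 difference of -0.59 (camera adjusted p = 1.07e-05, and 0.301 with an estimated correlation). The largest falls in it were in the Calvin cycle genes SBPASE, from 1798 ± 41.3 to 479 ± 47.6, and PRK, from 1934 ± 27.2 to 644 ± 18.9. Of 28 nuclear genes for plastid ribosomal proteins in the list 9 were measured. Of these 8 fell and 0 rose, with a median of -0.51 (camera adjusted p = 0.000736, and 0.342 with an estimated correlation). Adjusted over the list alone, 8 fell and 1 rose (log2 difference 0.12).

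Transcripts of the organelle genomes moved apart. Of 67 measured plastid genes 55 fell and 0 rose, with a median log2 difference of -0.45 (camera adjusted p = 1.17e-10; adjusted p = 0.236 with an estimated correlation). The photosystem genes psaA, psbB and psbD fell from 800 ± 124 to 257 ± 22.8, from 523 ± 42.2 to 192 ± 12.6 and from 462 ± 50.4 to 186 ± 5.84. Mitochondrial genes were picked by symbol (nad, cox, ccb or matR), so the rest of that genome was not examined. All 11 measured genes so picked rose, with a median of 0.96 (camera adjusted p = 1.46e-05, and 0.208 with an estimated correlation). With a pseudocount of 64 the median was 0.55. The respiratory chain genes cox1, nad4 and nad1 rose from 60.7 ± 8.27 to 233 ± 15.5, from 68.1 ± 9.65 to 179 ± 31.4 and from 35.8 ± 1.66 to 101 ± 16.5. A copy of the mitochondrial genome lies in the nuclear genome, and probe sets do not tell these sources apart.

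Genes for cytosolic ribosomal proteins rose together. Of 79 measured members 69 rose and 0 fell, with a median log2 difference of 0.42 (camera adjusted p = 1.45e-12; adjusted p = 0.301 with an estimated correlation). AT5G39850 rose most, from 98.0 ± 2.55 to 422 ± 42.9 (log2 difference 1.94), followed by AT2G32220, from 55.4 ± 9.38 to 153 ± 7.40, and AT1G15250, from 55.1 ± 13.5 to 148 ± 14.9. Ribosomal proteins are encoded by small families of similar genes, so a probe set may read more than 1 member. The directions of the ribosomal, photosynthesis and organelle lists were the same after quantile normalization.

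**Figure D2:**
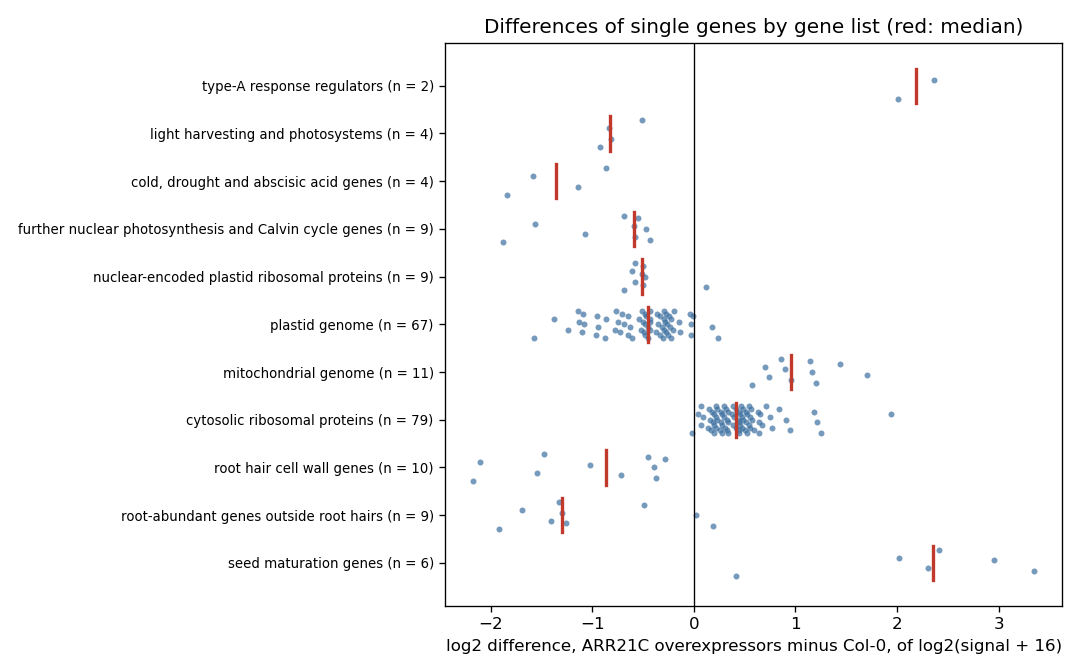
Log2 difference of log2(signal + 16), overexpressors minus Col-0, for each measured gene of 11 lists; points are genes that passed the filter on dim probe sets (6 of 25 seed maturation genes) and red lines their medians. The 79 cytosolic ribosomal protein genes have a median of 0.42 and the 11 mitochondrial genes, picked by symbol, one of 0.96. The 67 plastid genes have a median of -0.45 and the 4 cold and abscisic acid genes one of -1.36.

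Cold- and abscisic acid-responsive genes and anthocyanin genes were lower. Of 13 genes in the cold, drought and abscisic acid list only 4 were measured. All 4 fell, with the same count adjusted over the list alone (camera adjusted p = 0.000223, and 0.0455 with an estimated correlation). The chloroplast-protecting COR15A fell from 177 ± 6.24 to 38.4 ± 5.04 and COR15B from 156 ± 5.31 to 41.5 ± 2.28, and the dehydrin genes COR47 and LTI30 fell from 1090 ± 77.3 to 488 ± 33.7 and from 278 ± 16.9 to 146 ± 5.06. Of the flavonoid list, DFR, which makes leucoanthocyanidins, fell from 125 ± 13.4 to 22.4 ± 2.14 and UF3GT, an anthocyanin glycosyltransferase, from 35.6 ± 5.01 to 12.1 ± 5.24. The anthocyanin glucosyltransferase gene UGT75C1 (AT4G14090) was under the filter; without it, it was lower too, at 30.6 in Col-0 and 1.34 in the overexpressors.

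Hormone and stress genes of the other fixed lists moved in both directions. In the jasmonate list PDF1.2b fell with PDF1.2a, from 1655 ± 149 to 358 ± 25.5, and the third measured gene did not pass. The PDF1.2b probe set is of a type that can share probes with similar genes, so it may also read PDF1.2a. The auxin-conjugating genes GH3.3 and WES1 (GH3.5) rose from 64.2 ± 12.9 to 242 ± 23.9 and from 165 ± 10.7 to 263 ± 15.99, while IAA29 fell from 53.2 ± 1.98 to 37.4 ± 8.35; the IAA29 call was lost without overexpressor replicate 2 (log2 difference -0.27, limma adjusted p = 0.0649). The clock gene GI rose from 32.7 ± 5.28 to 135 ± 3.71. In the senescence list WRKY6 rose from 38.3 ± 2.51 to 125 ± 10.4 and WRKY53 from 43.4 ± 7.62 to 60.02 ± 7.51; the WRKY53 call was lost without Col-0 replicate 1 (0.27, limma adjusted p = 0.0744) or overexpressor replicate 3 (0.30, limma adjusted p = 0.0662). The defence regulator SAG101 rose from 44.0 ± 9.28 to 70.4 ± 3.11. BHLH101, of the iron list, had 12.6 ± 3.68 in Col-0 and 18.4 ± 3.86 in the overexpressors (limma adjusted p = 0.108). The reference gene TIP41L (AT4G34270) was higher, at 153 ± 3.98 against 107 ± 0.637. The lists of floral, seed storage, cell cycle, heat shock, phosphate and nitrate genes had 0 members named in the table used. The 1 named meristem gene was under the filter on dim probe sets. Adjusted over the list alone, each member of these lists lay on the same side of the threshold.

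Most measured root hair cell wall genes were lower, while the 2 measured genes of the fixed root list moved apart. In the fixed root list EXPA7, an expansin of root hairs, fell from 34.5 ± 6.16 to 21.4 ± 3.87, whereas PYK10, an abundant root beta-glucosidase, rose from 2136 ± 13.9 to 2437 ± 80.2. Of 10 measured root hair cell wall genes 9 fell and 0 rose, with a median log2 difference of -0.87 (camera adjusted p = 0.000102; adjusted p = 0.236 with an estimated correlation); with a pseudocount of 64 the median was -0.53. The peroxidase genes AT3G49960 and AT4G26010 fell in it from 59.3 ± 9.88 to 0.645 ± 0.00653 and from 321 ± 10.3 to 62.5 ± 5.64. The class III peroxidase list shares members with the root hair list, among them AT3G49960 and AT4G26010. Of its 41 measured genes 21 fell and 10 rose (camera adjusted p = 0.032, and 0.301 with an estimated correlation). That call was also lost without Col-0 replicate 1 (adjusted p = 0.0609) or replicate 3 (adjusted p = 0.0614). PRX52 rose most among them, from 26.1 ± 0.439 to 306 ± 12.7.

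Seed maturation transcripts were dim in Col-0, and many were higher in the overexpressors. In the fit without the filter on dim probe sets, 15 of 25 named members were higher, 0 were lower and 10 did not pass, with a median log2 difference of 0.59 and median signals of 2.64 in Col-0 and 12.5 in the overexpressors (camera adjusted p = 3.74e-06). Only 6 members passed the filter, which averages over both genotypes and so favours genes that were high in one of them; their median of 2.36 describes these genes and not the list (camera adjusted p = 0.000108; adjusted p = 0.208 with an estimated correlation), and it was 1.28 with a pseudocount of 64 and 3.82 with 1. Among them AT3G01570 went from 6.19 ± 2.28 to 210 ± 24.1, the cupin gene AT4G36700 from 1.64 ± 0.912 to 121 ± 13.3, the vicilin-like gene PAP85 from 9.67 ± 7.09 to 117 ± 11.2 and the oleosin gene OLEO3 from 10.5 ± 4.50 to 114 ± 7.54.

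Of the 3' to 5' ratios of control transcripts, a measure of RNA quality, that of the older GAPDH probe sets separated the genotypes. It was 1.11 ± 0.0635 in Col-0 and 0.812 ± 0.0502 in the overexpressors (exact two-sided permutation p = 0.1, the smallest possible, and 0.6 after adjustment over 6 ratios). With the r2 probe sets of GAPDH the ratio was higher in the overexpressors on average, at 0.942 ± 0.0490 against 0.865 ± 0.0304 (exact permutation p = 0.2). The older actin probe sets gave 4.50 ± 1.43 and 5.78 ± 0.746 (exact permutation p = 0.3), and the ubiquitin ratios and the r2 actin ratio had exact permutation p-values from 0.5 to 1.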

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

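Some control probe sets that the comparison of genes left out also differed between the genotypes, with each overexpressor array above each Col-0 array. The mean log2 signal of 5 GAPDH control probe sets was higher by 0.66 in the overexpressors, and that of 6 actin control probe sets by 0.35 (exact two-sided permutation p = 0.1 each, the smallest possible for 3 against 3 arrays). For 5 ubiquitin control probe sets the difference was 0.09 and the arrays overlapped. The spiked bacterial and phage controls were lower by 0.16 on the log2 scale (7.77 against 7.93) in the overexpressors, with each overexpressor array below each Col-0 array (exact two-sided permutation p = 0.1, the smallest possible).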

How the results depend on the processing

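Tests of the added lists were chosen only after the data had been seen. The counts of higher and lower probe sets stayed within 1.5 times their value under each alternative. No scaling moved the median of all probe sets by over 0.1, but each scaling aligns the arrays, so this was built in. It does not test the scaling itself. A scaling to the spiked controls, which were lower by 0.16 in the overexpressors, was not tried. Leaving out 1 array gave 4251 to 4508 higher and 4058 to 4518 lower probe sets. The pseudocount moved the counts of at least 2-fold changes, as it shrinks dim differences by construction: 362 higher and 427 lower with 64, and 1053 higher and 1295 lower with 1. Over the 107 named probe sets and the alternatives that gave a value, 1586 values kept their direction and side of the threshold. The other 3 lost significance (IAA29 without 1 array, WRKY53 without either of 2). Most of these probe sets were named because they had passed the threshold, so this stability was largely built in. With a correlation estimated per list, 1 of the fixed lists was lower (the cold list), and 0 added lists were higher and 0 lower, against 4 and 7 as reported; fry gave 9 and 16. These set tests ask different questions. Fry does not compare a list with other genes, and the camera runs differ in the correlation taken between genes. How much each of these contributes was not tested. Without the filter 3 fixed and 8 added lists were lower, the gains being the flavonoid list (adjusted p = 0.00161), which then had 4 measured members, and the BZIP family (adjusted p = 0.0218, against 0.127 as reported). The median of the seed maturation list went from 2.36 to 0.59 without the filter, where 25 members in place of 6 enter. The class III peroxidases also lost their call with a pseudocount of 1 (adjusted p = 0.0619), with the filter at the 50th percentile (0.0886), and without Col-0 replicate 1 (0.0609) or 3 (0.0614). Medians near 0 of symbol families that did not shift changed sign. Without the filter they were 0.014 for AGL, -0.038 for CYP, -0.0028 for PRA and 0.011 for TRM, and with a pseudocount of 64 -0.0061 for CYP. Leaving out 1 array gave medians of -0.212 to 0.0427 for AGL, -0.0075 to 0.0404 for CYP, -0.0853 to 0.0714 for TRM and -0.0585 to 0.103 for UBC; the cause was not tested. The ARR21 signal could be given under none of the alternatives, as it was not analysed here. No paired analysis was possible because the labels give the arrays no shared replicate numbers. Signal over background limits probe sets such as those of AT4G36700 and 250612_s_at, whose Col-0 signals lay under the pseudocount. It also limits AT3G49960, whose overexpressor signal did.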

Other observations

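The tests of organelle RNA capture and of scaling that depends on the signal, and the lists behind the tests of ribosomal, photosynthesis and root genes were chosen only after the largest changes had been seen.

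Among symbol families, the beta-glucosidase genes (BGLU) were mostly higher and the tau-class glutathione transferases (GSTU) mostly lower. Of 11 BGLU genes 8 rose and 1 fell (camera adjusted p = 0.00602; adjusted p = 0.301 with an estimated correlation). BGLU45 and BGLU46, which act on monolignol glucosides, rose from 12.8 ± 2.15 to 108 ± 2.83 and from 36.5 ± 2.31 to 158 ± 15.2, and BGLU25 from 109 ± 5.34 to 512 ± 10.7, while BGLU33 fell from 64.2 ± 7.43 to 10.3 ± 0.636. Of 8 GSTU genes 6 fell and 1 rose (camera adjusted p = 0.0153; adjusted p = 0.236 with an estimated correlation). GSTU20 fell from 699 ± 48.6 to 239 ± 25.7 and GSTU18 from 206 ± 17.56 to 75.5 ± 2.38, while GSTU25 rose from 18.1 ± 5.77 to 49.9 ± 9.56. The other symbol families had camera adjusted p-values from 0.127 to 0.9, of which the BZIP family passed without the filter on dim probe sets (adjusted p = 0.0218).

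Histone genes and CC-type glutaredoxins did not shift as lists in camera (camera adjusted p = 0.447 and 0.658). In fry, which does not compare a list with other genes, the histone list was higher (fry adjusted p = 0.0102). The glutaredoxins did not pass there either (fry adjusted p = 0.494). Of 7 histone genes 3 rose and 1 fell, and HTB4 rose from 277 ± 11.6 to 362 ± 28.7. Of 15 CC-type glutaredoxins 6 rose and 3 fell, the latter including AT1G06830, from 119 ± 6.32 to 33.3 ± 2.31.

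With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The genotypes gave 9247 probe sets past the threshold and 1581 of at least 2-fold, and the highest of the other splits gave 0 of either in limma; at an unadjusted p under 0.05 the other splits gave 50 to 249. In each case 1 of the 10 splits reached the real value. For the 2 fixed lists 5 of the 10 splits shifted both, the highest other being 2, and for the added lists 1 split reached 11, the highest other being 7. Each of these other splits sets 2 arrays of one genotype and 1 of the other against the rest, so part of a difference between genotypes stays in it. The rest of that difference lies within each side and raises the spread there, which holds down the calls in limma. The counts of 0 were therefore largely built in and do not measure what chance gives.

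Cytosolic ribosomal protein genes were higher while nuclear photosynthesis genes were lower. The medians of these lists stayed apart by at least 0.98 on the log2 scale under the scalings tried, but 1 factor per array moves both lists alike, so median centring tested nothing here. A scaling that depends on the signal was tested by taking from each gene the median of the 200 genes nearest to it in mean signal outside both lists. The ribosomal median was then 0.37 (bootstrap 95% interval over genes 0.28 to 0.42) and the photosynthesis median -0.58 (-1.63 to -0.51), a gap of 0.95, which argues against such scaling as the whole cause; genes are not independent replicates. The genotype, or growth conditions or batches that follow it, may account for the pattern and were not tested apart.

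Transcripts of the mitochondrial genes picked by symbol were higher and plastid transcripts lower. A general change in the capture of organelle RNA without poly(A) tails would move both the same way, but their medians were 0.96 and -0.45, 1.41 apart, with 11 of 11 mitochondrial genes higher and 55 of 67 plastid genes lower. These are the values that prompted the question, so they argue only against such capture as the cause of both shifts, and capture may still account for one of them. Cross-hybridization of the nuclear copy of the mitochondrial genome was not tested, and a difference in organelle number or transcription between genotypes may be involved as a hypothesis.

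The fall of root hair cell wall genes may come from a lower share of root tissue in the whole-plant samples. A list of root-abundant genes outside root hairs was written before the values of its members were seen, except PYK10, but after the count of class III peroxidases, which include 5 of its 9 measured genes, was known. Of its 9 measured genes 7 fell and 1 rose (camera adjusted p = 0.000777; adjusted p = 0.236 with an estimated correlation). Its median was -1.30, against -0.87 for the root hair genes (permutation p = 0.519 for the difference of medians, which does not show that they are alike). With a pseudocount of 64 these medians were -0.75 and -0.53. A fall of the list is what a lower share predicts. But a lower share of root means a higher share of shoot, and photosynthesis and plastid transcripts fell in the same samples. The list medians were -0.83 for light harvesting, -0.59 for further photosynthesis, -0.51 for plastid ribosomal proteins and -0.45 for plastid genes. A lower share alone does not account for these falls. AT5G66390 fell from 68.9 ± 6.30 to 6.54 ± 0.986 and AT4G30170 from 352 ± 23.1 to 98.5 ± 12.0. The most abundant members did not fall, with PYK10 at 2437 against 2136 and JAL22 at 419 against 411, so a lower share alone leaves these open. Without the peroxidases the median over the 4 remaining genes was -0.64, with a range from -1.33 to 0.19. The root hair list also holds class III peroxidases, among them AT3G49960 and AT4G26010, and these were not left out of it. A change of peroxidase expression within roots was not tested apart.

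Genes that rose at least 2-fold lay beside each other on the chromosomes more often than random order gives. Among 2952 pairs of adjacent measured genes, 11 pairs had both members higher by at least 2-fold, against a median of 4 and a highest of 14 in 10000 permutations (one-sided permutation p = 0.006). Of the 11 pairs, 5 are neighbours of one gene family, among them BGLU45 with BGLU46 and AT5G38160 with AT5G38170, whose probe sets might read each other. The other 6 pairs alone lie within the permuted range, whose 97.5th percentile was 9. That range counts neighbours of one family too, so it cannot decide whether the excess over random order rests on them. Which pairs are of one family was judged after their values were seen.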
